A study of Homo sapiens with 12 samples.

How the data were processed

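RNA was measured by sequencing of poly(A) libraries from MOLM13 and OCIAML5 cells, per the labels made with a stranded mRNA kit after lentiviral hairpin delivery. The deposited tables hold raw counts per gene, 1 table with 8 libraries for PSPC1 and 1 with 4 libraries for PU.1, and each lists 60648 genes. Per the submitters' processing notes the tools were Trim Galore 0.6.7, STAR 2.7.10a, HTSeq 2.0.2 and DESeq2 1.36.0 with GRCh38, whose roles are not stated. The annotation release and the strand setting of the counting are not given in the sources used here. Totals ran from 15.4 to 22.8 M counts per library in the PSPC1 table and from 26.3 to 39.7 M in the PU.1 table.

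The 12 libraries were placed in 6 groups of 2 from the labels. Counts were analysed in R 4.3.3 with edgeR 4.0.16, using filterByExpr, TMM scaling and quasi-likelihood F tests. The PSPC1 table was fitted as 1 model of 4 groups with 4 residual degrees of freedom, the PU.1 table as a model of 2 groups with 2, and the 8 OCIAML5 libraries were joined to compare both knockdowns. There were 5 comparisons: PSPC1 knockdown in MOLM13, PSPC1 knockdown in OCIAML5, PU.1 knockdown in OCIAML5, the difference of the PSPC1 effect between the lines, and the difference between the PU.1 and PSPC1 effects in OCIAML5. P-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The biological coefficient of variation was 4.7%, 4.1% and 4.5% in the PSPC1, PU.1 and joined fits. Between the libraries of a group the variance was 2.62 to 4.97 times that of counting alone.

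Before the data were examined, 35 gene lists, the comparisons, the alternatives and the rule for naming genes were fixed. Lists with at least 3 measured genes were tested with camera in limma 3.58.1, which compares a list with all other genes, with a preset correlation between genes of 0.01, and adjusted over the lists of a comparison. The alternatives for lists were an estimated correlation and fry. The first test of fry asks whether the genes of a list move on balance one way and its mixed test whether they move in either direction, and neither compares them with other genes. The genes named were PSPC1, SPI1 and NDC1. To these were added the 8 largest changes each way per knockdown among genes that passed, with a mean of at least 5 CPM in the higher group and both knockdown libraries beyond both controls, and the 3 members with the smallest adjusted p of up to 10 called lists. Also named were the 5 genes each way that passed in all 3 knockdowns with the largest smallest change, and the 5 largest differences each way per difference test. Other genes were chosen after their values were seen, and the text says so where they appear. List medians were also computed with a floor of 3 counts over a group.

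The alternatives were DESeq2 1.42.0, RLE size factors, no low-count filter, a filter of 1 CPM in at least 2 libraries, a block for the replicate number, the 4 libraries of a line alone, an adjusted p of 0.01, a 2-fold minimum, leaving out each library in turn, and, chosen after the data were seen, scaling by library size alone and RLE size factors for lists. The method was tested on simulated data with 50 seeded genes per size: a log2 change of 1 was recovered for 82%, 90%, 96%, 80% and 90% of them in the 5 comparisons in turn. A log2 change of 0.3 was recovered for 28%, 18%, 30%, 4% and 16%. The share of called genes that carried no seeded change was 9.19%, 3.55%, 2.14%, 5.6% and 4.58%, so PSPC1 knockdown in MOLM13 and the difference between the lines ran above the threshold. Apart from a seeded list, only 200 genes changed in each simulation, whereas 30.5% to 60.4% of the genes tested were called in the data. With so few changes the adjusted threshold is harder to pass, so these shares need not hold for the data. Gene positions are from GENCODE on GRCh38. Python 3.11.15 and matplotlib 3.10.9 drew the plots. Protein levels, splicing and isoforms were not analysed here.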

Results

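Messenger RNA was sequenced in MOLM13 and OCIAML5, human acute myeloid leukemia cell lines that carried lentiviral hairpins against PSPC1, an RNA-binding protein of nuclear paraspeckles, or against SPI1, the gene of the myeloid transcription factor PU.1. The 12 libraries formed 6 groups of 2 libraries each. Control and PSPC1-knockdown libraries came from both lines, and control and PU.1-knockdown libraries came from OCIAML5 in a second experiment with its own controls. Total counts were 22.8 and 17.5 M in the MOLM13 controls and 15.4 and 17.2 M after PSPC1 knockdown in MOLM13. They were 18.5 and 15.8 M in the OCIAML5 controls and 22.7 and 17.1 M after PSPC1 knockdown in OCIAML5. In the PU.1 experiment they were 33.4 and 39.7 M in the controls and 26.3 and 33.9 M after knockdown. The tables listed 60648 genes, of which 16457 were tested for PSPC1 knockdown, 16861 for PU.1 knockdown and 17159 in the joined OCIAML5 libraries. The labels do not say whether the libraries of a group came from separate cultures or hairpins, so the p-values measure only the spread between these libraries, which may be technical. Levels are in CPM, each count divided by its scaled library size, given as mean ± SD with n = 2, and are relative, because the total RNA per cell is not known.

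The level of the targeted gene in each library came first. PSPC1 (GRCh38 chromosome 13, 19674752 to 19783019) stood at 130 and 135 CPM in the MOLM13 controls and at 27.1 and 27.7 CPM after its knockdown, a log2 fold change of -2.27 ± 0.072 (SE; adjusted p = 3.5e-31). In OCIAML5 it stood at 99.1 and 98.8 CPM in the controls and at 18.9 and 19.2 CPM after knockdown, a log2 fold change of -2.38 ± 0.075 (SE; adjusted p = 2.9e-31). SPI1 (chromosome 11, 47354860 to 47378576) stood at 227 and 204 CPM in the controls of the PU.1 experiment and at 47.5 and 46.2 CPM after PU.1 knockdown, a log2 fold change of -2.20 ± 0.053 (SE; adjusted p = 4.2e-46). PSPC1 also fell after PU.1 knockdown, from 106 and 113 CPM to 59.8 and 58.2 CPM, a log2 fold change of -0.89 ± 0.055 (SE; adjusted p = 2.1e-23). SPI1 rose after PSPC1 knockdown in MOLM13, from 254 and 245 CPM to 326 and 352 CPM, a log2 fold change of 0.44 ± 0.05 (SE; adjusted p = 7.9e-11). In OCIAML5 SPI1 was at 201 and 180 CPM in the controls and 201 and 217 CPM after PSPC1 knockdown, a log2 fold change of 0.13 (adjusted p = 0.023). That small change lost its call with DESeq2 (adjusted p = 0.053) and in a fit of these 4 OCIAML5 libraries alone (adjusted p = 0.059). It was 0.05 (adjusted p = 0.47) without control replicate 2 and 0.07 (adjusted p = 0.34) without knockdown replicate 2. Among the genes singled out for each comparison, all 76 that passed after PSPC1 knockdown in MOLM13, all 71 in OCIAML5 and all 77 after PU.1 knockdown had both knockdown libraries beyond both controls, which the naming rule itself required of the largest changes. PSPC1 overlaps an antisense gene, PSPC1-AS2, and the strand setting of the counting is not given in the sources used here.

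**Figure D1:**
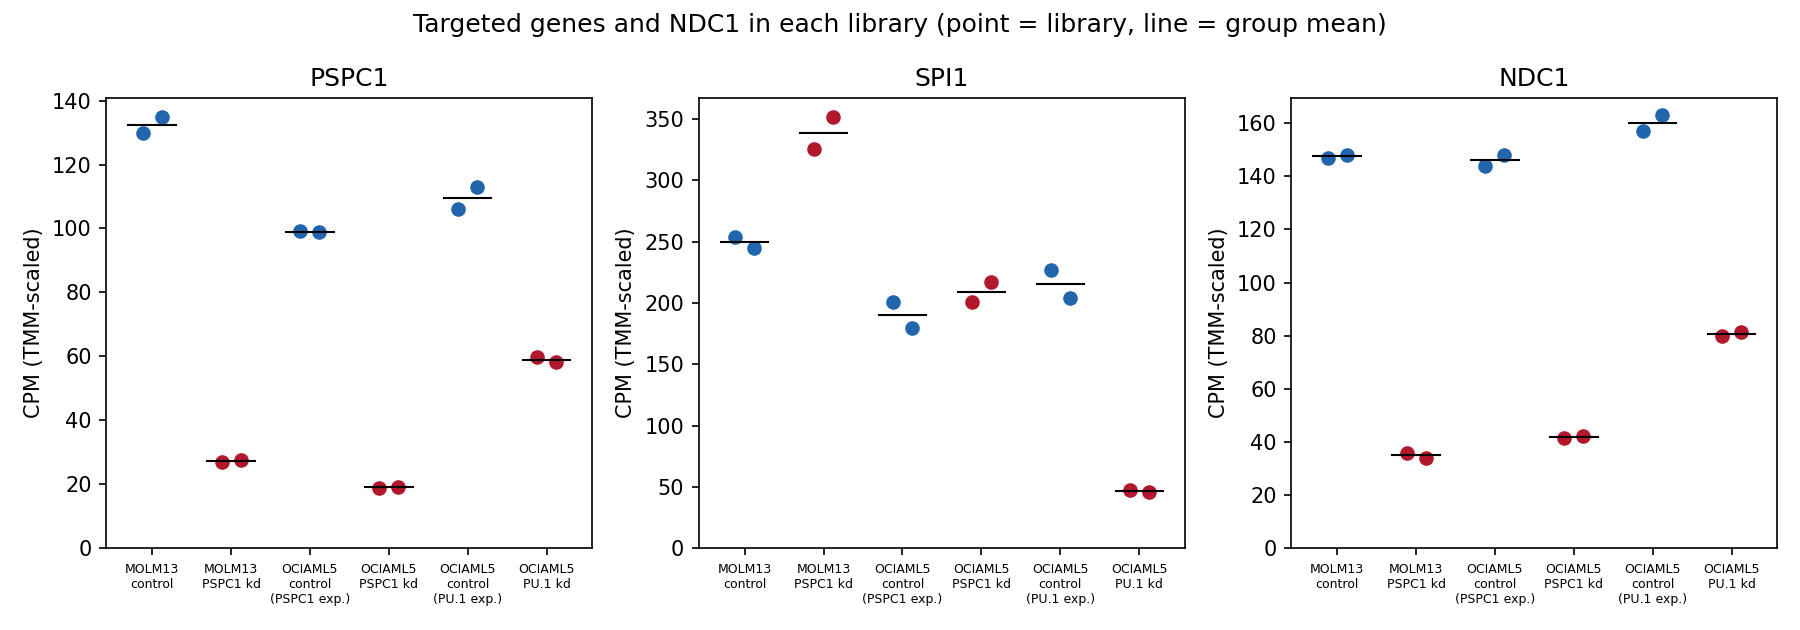
Level in CPM of PSPC1, SPI1 and NDC1 in each of the 12 libraries, by group, with points for libraries and lines for group means. PSPC1 fell in all 3 knockdowns, to 27.4, 19.1 and 59 CPM on average, and SPI1 fell to 46.9 CPM after PU.1 knockdown.

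The comparison of PSPC1 knockdown with control in MOLM13 asked what the loss of PSPC1 changes in this line. DNA replication, mitosis and DNA repair genes fell together, as did ribosome biogenesis factors, nuclear pore proteins and targets of ATF4, the transcription factor of the amino acid stress response. Interferon-stimulated genes and p53 targets rose. MKI67, the proliferation marker (chromosome 10, 128096659 to 128126385), fell from 612 ± 8 to 60.2 ± 4.7 CPM (log2 fold change -3.34). MCM4, a subunit of the replicative helicase (chromosome 8, 47960185 to 47978160), fell from 907 ± 19 to 125 ± 1.8 CPM (-2.86). RRM2, a subunit of ribonucleotide reductase, fell from 245 ± 10 to 30.8 ± 2.2 CPM (-2.99). CDKN1A, the p53-induced cell cycle inhibitor p21 (chromosome 6, 36676460 to 36687339), rose from 363 ± 13 to 1120 ± 26 CPM (1.62). In all, 9388 genes (57% of those tested) passed an adjusted p of 0.05, 4537 higher and 4851 lower, and 1629 of the higher and 1796 of the lower changed at least 2-fold.

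All 28 measured DNA replication genes fell in MOLM13 (median log2 fold change -2.55, adjusted p = 5.7e-32), and 26 of 27 mitosis genes fell (-2.48, adjusted p = 7.5e-29), including CENPF at -2.89 and TOP2A at -2.61. Of 24 DNA repair genes, 22 fell and 2 rose (median -1.63, adjusted p = 1.9e-12), with BLM, a helicase, from 109 ± 1.5 to 16.9 ± 1.5 CPM. NDC1, a membrane nucleoporin (chromosome 1, 53765460 to 53838860), fell from 148 ± 1.1 to 34.9 ± 1.3 CPM (-2.08), and 25 of 28 nuclear pore genes fell (median -0.57, adjusted p = 1.3e-09) while 1 rose. Of 32 ribosome biogenesis factors, 31 fell (median -0.90, adjusted p = 1.4e-17), and NPM1, nucleophosmin, fell from 1870 ± 68 to 786 ± 22 CPM. Of 24 ATF4 targets, 23 fell (median -1.53, adjusted p = 2.9e-16). SLC7A5, a transporter of large neutral amino acids (chromosome 16, 87830023 to 87869488), fell from 602 ± 4.3 to 57.8 ± 5.1 CPM. PSAT1 and PHGDH, enzymes of serine synthesis, fell from 336 ± 0.48 to 35.3 ± 3.3 CPM and from 173 ± 8.2 to 15.9 ± 1.3 CPM. In each of these lists the counts adjusted over the list alone were the same.

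Of 33 interferon-stimulated genes, 30 rose in MOLM13 and none fell (median 1.87, adjusted p = 2.9e-13; the same counts adjusted over the list alone). SAMD9 rose from 43.1 ± 3.2 to 128 ± 5.4 CPM, and IFI6 from 5.68 to 51.1 CPM. Of 24 p53 targets, 18 rose and none fell, 20 adjusted over the list alone (median 0.76, adjusted p = 3.1e-09), among them RRM2B at 1.09 and TNFRSF10B at 0.99. Of 16 replication-dependent histone genes, 11 rose and 1 fell (median 1.66, adjusted p = 0.00038), and H2AC6 rose from 13.1 ± 1.4 to 94.2 ± 1.5 CPM. In the same libraries the summed level of this list, whose members include close paralogs, went from 43.5 to 178 CPM, that of other RNAs without a poly(A) tail from 34.8 to 46.2 CPM, and the share of counts from mitochondrial messages from 7.54 ± 0.29% to 9.52 ± 0.014%. Of 13 azurophil granule genes, a list centred on neutrophil granule proteins, 10 fell and 2 rose (median -1.62, adjusted p = 8.8e-05). CTSG and PRTN3, chosen after their values were seen, fell from 152 to 18.4 CPM and from 2040 to 665 CPM, while ELANE and CFD rose by 0.28 and 0.89 on the log2 scale. Of 16 STAT5 targets, 12 fell and 1 rose (median -1.36, or -1.06 with a floor of 3 counts, adjusted p = 0.00032), with CCND2, chosen in the same way, from 172 to 23.7 CPM. With an estimated correlation 11 lists kept their call in MOLM13, those named so far, the last 3 of them with adjusted p from 0.043 to 0.049.

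A further 9 lists were called in MOLM13 with the preset correlation but lost their call with an estimated one. Of 18 paraspeckle genes, 13 fell and 2 rose (median -0.46, adjusted p = 1.3e-05, and adjusted p = 0.073 with an estimated correlation). NUDT21, a cleavage factor, fell by 1.46 on the log2 scale, while NEAT1, the RNA scaffold of paraspeckles (chromosome 11, 65422774 to 65445540; chosen after its values were seen), rose from 178 ± 3.4 to 409 ± 6.6 CPM. Of 22 cholesterol synthesis genes, 16 fell and 1 rose (median -0.58, adjusted p = 1.4e-05, and adjusted p = 0.077 with an estimated correlation), with DHCR7 at -2.05. Of 18 endoplasmic reticulum chaperone genes, 12 fell and 3 rose (median -0.51, adjusted p = 0.00028, and adjusted p = 0.081 with an estimated correlation). Of 14 heat shock genes, 10 fell and 3 rose (median -0.46, adjusted p = 3e-04, and adjusted p = 0.077 with an estimated correlation). Of 22 glycolysis and hypoxia genes, 14 fell and 3 rose (median -0.62, adjusted p = 3e-04, and adjusted p = 0.13 with an estimated correlation). Cytosolic ribosomal protein genes rose in 28 of 36 cases, 29 adjusted over the list alone, and fell in 2 (median 0.25, adjusted p = 3.7e-05, and adjusted p = 0.55 with an estimated correlation). Mitochondrially encoded genes rose in 12 of 13 cases (median 0.24, adjusted p = 0.0015, and adjusted p = 0.53 with an estimated correlation). PU.1-dependent myeloid genes went both ways, with 13 of 30 higher and 6 lower, 15 and 6 adjusted over the list alone; their median was 0.09, their mean -0.01 and the test pointed up (adjusted p = 0.022, and adjusted p = 0.17 with an estimated correlation). MYC, MYB and partners fell in 5 of 9 cases, 6 adjusted over the list alone, and rose in 2 (median -0.24, adjusted p = 0.038, and adjusted p = 0.15 with an estimated correlation). MYC and BCL2, chosen after their values were seen, fell from 601 to 153 CPM and from 221 to 77.8 CPM.

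The largest falls in MOLM13 among genes that pass the naming rule were those of E2F2, from 33.9 ± 0.51 to 1.62 ± 0.61 CPM, WNT7B, from 18.2 ± 1.7 to 1.03 ± 0.041 CPM, TBL1X, from 49.9 ± 0.57 to 2.97 ± 0.94 CPM, and CDC6, the replication licensing factor, from 74.4 ± 3.9 to 4.63 ± 0.91 CPM. OLIG2, CDKN3, SLC7A11 and MND1 completed the 8, with log2 fold changes from -3.96 to -3.76. The 8 largest rises were those of IFI44L, IFIT1, OAS3, IFI6, CCDC194, SIGLEC1, PATL2 and TNFRSF10C, several of them interferon-stimulated. SIGLEC1, a macrophage lectin, rose from 0.515 ± 0.31 to 9.58 ± 0.038 CPM and PATL2 from 1.12 ± 0.23 to 12 ± 0.49 CPM. Lists without a call in MOLM13 were oxidative phosphorylation (adjusted p = 0.2), later granule and neutrophil genes (0.19), T and NK lymphocyte genes (0.19), the HOXA and MEIS1 program (0.29), leukemic stem cell score genes (0.46), MHC class II (0.5), NF-kB (0.5), mast cell genes (0.5), immediate early genes (0.52), apoptosis regulators (0.55), B lymphocyte genes (0.64), monocyte and macrophage genes (0.69) and megakaryocyte genes (0.95). Erythroid and epithelial lists had 2 measured genes and were not tested.

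The same comparison in OCIAML5, which was grown with GM-CSF, asked what PSPC1 loss changes in a second line. Proliferation genes and ATF4 targets fell and p53 targets and interferon-stimulated genes rose here too. CDKN1A rose from 181 ± 2.9 to 1250 ± 49 CPM (log2 fold change 2.78), MKI67 fell from 888 ± 56 to 232 ± 6.2 CPM (-1.94) and SLC7A5 fell from 748 ± 10 to 191 ± 2.7 CPM (-1.97). CHAC1, a glutathione-degrading enzyme induced by ATF4, fell from 33.1 ± 1.7 to 1.47 ± 0.51 CPM. In the OCIAML5 controls of the PU.1 experiment CHAC1 stood at only 0.718 CPM. H2AC6, a histone gene, rose from 4.69 ± 0.79 to 101 ± 4.2 CPM. Of 16457 genes tested, 9214 (56%) passed, 4533 higher and 4681 lower, with 1558 and 1578 at 2-fold.

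Of 28 DNA replication genes, 27 fell in OCIAML5, 28 adjusted over the list alone (median -1.73, adjusted p = 8.5e-24), and 26 of 27 mitosis genes fell (-1.45, adjusted p = 8e-21). CDT1, a replication licensing factor, fell from 143 ± 0.36 to 23.7 ± 0.17 CPM. Of 24 p53 targets, 23 rose and none fell (median 1.12, adjusted p = 6.6e-19), with TP53INP1 from 30 ± 1.7 to 173 ± 4.4 CPM. Of 24 ATF4 targets, 22 fell, 23 adjusted over the list alone (median -1.71, adjusted p = 1.8e-17), with PSAT1 from 379 ± 16 to 45.2 ± 0.9 CPM. Set against the OCIAML5 controls of the PU.1 experiment, a comparison chosen after the results were seen, their median was -0.38 (SE 0.2). The size of this fall therefore depends on which controls are used. Of 32 ribosome biogenesis factors, 30 fell, while 1 rose adjusted over the list alone (median -0.68, adjusted p = 6.6e-13). Of 24 DNA repair genes, 20 fell and 2 rose (median -1.29, adjusted p = 2.9e-10). BRCA1 and BRCA2 fell by 1.61 and 1.79 on the log2 scale. Cholesterol synthesis genes fell in 18 of 22 cases and rose in 1 (median -0.96, adjusted p = 1.6e-08), with SQLE from 193 ± 2.7 to 75.5 ± 0.95 CPM. Of 33 interferon-stimulated genes, 26 rose and 2 fell (median 1.19, adjusted p = 2.2e-08). Of 28 nuclear pore genes, 23 fell and 2 rose (median -0.47, adjusted p = 7.8e-08), and NDC1 fell from 146 ± 2.7 to 41.8 ± 0.47 CPM.

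Replication-dependent histone genes rose in 13 of 16 cases in OCIAML5 and fell in none (median 3.04, adjusted p = 6.6e-07). H2BC5 rose from 4.03 ± 1 to 34.5 ± 3.1 CPM and H4C8 from 1.53 ± 0.25 to 20.1 ± 0.09 CPM. In these libraries the summed histone level went from 24.5 to 242 CPM, that of other RNAs without a poly(A) tail from 9.25 to 9.37 CPM, and the mitochondrial share from 8.87 ± 0.82% to 11.2 ± 0.071%. These 10 lists kept their call with an estimated correlation, with adjusted p of 0.042 for cholesterol synthesis. Glycolysis and hypoxia genes fell in 14 of 22 cases and rose in 2, 15 and 3 adjusted over the list alone (median -0.68, adjusted p = 1.7e-05, and adjusted p = 0.12 with an estimated correlation). Paraspeckle genes fell in 11 of 18 cases, 12 adjusted over the list alone, and rose in 3 (median -0.38, adjusted p = 0.0016, and adjusted p = 0.16 with an estimated correlation), NEAT1 being higher again, at 316 against 205 CPM. MHC class II genes fell in 7 of 11 cases (median -0.25, adjusted p = 0.043, and adjusted p = 0.17 with an estimated correlation), with CIITA, their master regulator, from 167 ± 4.1 to 33.9 ± 2.2 CPM. Azurophil granule genes, with 7 of 13 lower and 2 higher, were not called (adjusted p = 0.14); their median was -1.65 as fitted and -0.45 with a floor of 3 counts.

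Among single genes in OCIAML5, FLT3, a receptor kinase, IRF8, a transcription factor of monocytic cells, and MYC, all chosen after their values were seen, fell from 239 to 25.7 CPM, from 348 to 97.1 CPM and from 582 to 192 CPM. The largest falls by the naming rule were those of SLC12A8, from 12 ± 0.58 to 0.368 ± 0.34 CPM, IL2RA, from 8.95 ± 0.67 to 0.313 ± 0.029 CPM, IL7R, from 7.24 ± 1.6 to 0.285 ± 0.01 CPM, CHAC1, GABRA4, KIF17, from 26.8 ± 0.23 to 1.46 ± 0.29 CPM, SIGLEC6, from 80.8 ± 5.6 to 4.73 ± 2.2 CPM, and DIPK1C. The largest rises were those of IFI44, H2BC6, HFE, TTYH1, H2AC6, IFI44L, PCDHGA10 and MIR22HG. HFE, the hemochromatosis gene, rose from 0.226 ± 0.14 to 7.12 ± 0.8 CPM. PCDHGA10 shares its span and strand with other protocadherin gamma genes, and MIR22HG overlaps WDR81 on the opposite strand. Lists without a call were HOXA and MEIS1 (adjusted p = 0.059), apoptosis regulators (0.11), NF-kB (0.11), mitochondrially encoded genes (0.11), MYC, MYB and partners (0.14), STAT5 targets (0.14), chaperones of the endoplasmic reticulum (0.14), cytosolic ribosomal proteins (0.18), heat shock (0.22), T and NK lymphocyte genes (0.48), immediate early genes (0.51), mast cell genes (0.51), B lymphocyte genes (0.51), leukemic stem cell score genes (0.68), PU.1-dependent genes (0.77), and later granule, monocyte, oxidative phosphorylation and megakaryocyte genes (0.8 each). With 2 measured genes each, the erythroid and epithelial lists were not tested here either.

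PU.1 knockdown in OCIAML5, against its own controls, asked what the loss of PU.1 changes. Most monocyte genes and the MHC class II genes fell and most azurophil granule genes rose, although with an estimated correlation these lists lost their calls (adjusted p from 0.21 to 0.32). CSF1R, the receptor for macrophage colony-stimulating factor (chromosome 5, 150053291 to 150113372), fell from 167 ± 4.2 to 3.22 ± 0.45 CPM (log2 fold change -5.68). MPEG1, a macrophage perforin (chromosome 11, 59208510 to 59212951), fell from 243 ± 7.8 to 2.02 ± 0.061 CPM (-6.91), and CD74, the MHC class II invariant chain, fell from 1430 ± 60 to 300 ± 4.4 CPM (-2.25). THBS1, thrombospondin (chromosome 15, 39581079 to 39599466), rose from 0.878 ± 0.033 to 182 ± 1.9 CPM (7.69), and CFD, a serine protease of granules, rose from 24.7 ± 3 to 194 ± 7.3 CPM (2.98). Of 16861 genes tested, 10189 (60.4%) passed, 4983 higher and 5206 lower, with 1885 and 1069 at 2-fold. Scaling by library size alone shifted the median log2 fold change of all genes by 0.152 and turned the split into 6583 higher and 3995 lower, so the balance between rises and falls rests on the normalisation. With the same scaling the split was 4902 higher and 4563 lower after PSPC1 knockdown in MOLM13 and 5201 and 4183 in OCIAML5.

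All 10 measured MHC class II genes fell after PU.1 knockdown (median -1.97, adjusted p = 4.7e-18, and 0.21 with an estimated correlation). HLA-DRA fell from 268 ± 9.7 to 61.5 ± 0.36 CPM and CIITA from 110 ± 1.8 to 19.1 ± 0.18 CPM. Of 26 PU.1-dependent myeloid genes, 20 fell and 5 rose (median -1.15, adjusted p = 1.5e-11, and 0.21 with an estimated correlation). CD180 fell from 121 ± 1.8 to 7.76 ± 1.5 CPM. Of 20 monocyte and macrophage genes, 13 fell and 6 rose (median -1.45, adjusted p = 5.7e-05, and 0.32 with an estimated correlation), with LYZ, lysozyme, from 69.3 to 19.3 CPM (chosen after its values were seen). Azurophil granule genes rose in 12 of 14 cases and fell in 1 (median 1.35, adjusted p = 7e-12, and 0.21 with an estimated correlation). AZU1, azurocidin, rose from 3.71 ± 0.94 to 40.3 ± 1.3 CPM, while MPO, chosen after its values were seen, fell by 0.63 on the log2 scale. IGLL1, which has close paralogs, rose from 0.577 ± 0.0092 to 20.3 ± 0.54 CPM. It encodes a surrogate immunoglobulin light chain rather than a granule protein. Of 8 later granule and neutrophil genes, 4 rose and 2 fell, 4 and 3 adjusted over the list alone (median 0.48, adjusted p = 0.012, and 0.29 with an estimated correlation), ANXA1, chosen likewise, rising from 33.5 to 390 CPM. Of 8 mast cell, basophil and eosinophil genes, 5 rose and 2 fell (median 1.69, adjusted p = 0.01, and 0.42 with an estimated correlation). Among them GATA2, chosen like KIT after its values were seen, rose from 44.6 to 234 CPM and HDC stood at 0.0265 and 6.37 CPM, while FCER1A, a chain of the IgE receptor, fell from 4.82 to 0.1 CPM, and KIT, the stem cell factor receptor, went from 0.564 to 0.06 CPM.

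Proliferation genes fell after PU.1 knockdown as well. All 27 mitosis genes fell (median -0.97, adjusted p = 4.5e-24, and 0.21 with an estimated correlation), as did 27 of 28 DNA replication genes (-0.96, adjusted p = 1e-20, and 0.21 with an estimated correlation), 20 of 24 DNA repair genes with 1 higher (-0.79, adjusted p = 1.4e-07, and 0.33 with an estimated correlation) and 28 of 32 ribosome biogenesis factors with 1 higher (-0.50, adjusted p = 2.5e-07, and 0.21 with an estimated correlation). Of 25 p53 targets, 19 rose, 20 adjusted over the list alone, and 2 fell (median 0.45, adjusted p = 2.4e-08, and 0.21 with an estimated correlation), and CDKN1A rose from 336 ± 7.8 to 1030 ± 34 CPM. Cholesterol synthesis genes fell in 16 of 22 cases, 17 adjusted over the list alone, and rose in 2 (median -0.67, adjusted p = 3.7e-06, and 0.25 with an estimated correlation), with SQLE at -1.42. Oxidative phosphorylation genes fell in 26 of 31 cases and rose in 1 (median -0.50, adjusted p = 3.7e-06, and 0.33 with an estimated correlation), CYC1, cytochrome c1, from 311 ± 16 to 178 ± 2.8 CPM. Nuclear pore genes fell in 25 of 28 cases and rose in 1 (median -0.48, adjusted p = 3.8e-06, and 0.21 with an estimated correlation), and NDC1 fell from 160 ± 3.9 to 80.5 ± 1.1 CPM. Heat shock genes fell in 13 of 14 cases (median -0.46, adjusted p = 7.5e-05, and 0.25 with an estimated correlation). Paraspeckle genes fell in 14 of 18 cases, 15 adjusted over the list alone, and rose in 1 (median -0.42, adjusted p = 8.8e-05, and 0.32 with an estimated correlation), the riser being NEAT1, from 192 to 332 CPM. Interferon-stimulated genes rose in 22 of 33 cases, 23 adjusted over the list alone, and fell in 1 (median 0.68, adjusted p = 1e-04, and 0.21 with an estimated correlation), with IFI44L from 1.23 ± 0.17 to 15.7 ± 1.4 CPM. Histone genes rose in 9 of 15 cases (median 1.28, adjusted p = 0.013, and 0.33 with an estimated correlation). Their summed level went from 24.2 to 76.1 CPM while that of other RNAs without a poly(A) tail went from 14.4 to 10.8 CPM, and the mitochondrial share was 7.9% in both controls and 8.24 ± 0.5% after knockdown. MYC, MYB and partners rose in 5 of 9 cases (median 0.35, adjusted p = 0.025, and 0.33 with an estimated correlation). None of the 19 lists called after PU.1 knockdown kept its call with an estimated correlation, where 2 residual degrees of freedom were left: every such adjusted p lay between 0.21 and 0.42.

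ATF4 targets showed no common direction after PU.1 knockdown, with 9 of 24 higher and 11 lower; their median was -0.13, or 0.02 with scaling by library size (adjusted p = 0.48). SLC7A5 was at 560 ± 21 and 550 ± 6.7 CPM (adjusted p = 0.59), PSAT1 fell from 119 ± 2.5 to 43.5 ± 2.1 CPM and SLC7A11, the cystine transporter, rose from 10.6 ± 1.7 to 36.2 ± 1.5 CPM. By the naming rule the largest falls were those of TIFAB (chromosome 5, 135444218 to 135452399), from 37.7 ± 1.2 to 0.0837 CPM, MPEG1, RXFP1, DHRS9, from 22.6 ± 0.08 to 0.258 ± 0.11 CPM, GAPT, MS4A4A, CLEC10A and DKK2. The largest rises were those of FPR1, THBS1, HDC, SLC6A13, CR1, the complement receptor, from 0.487 ± 0.061 to 58.6 ± 3.6 CPM, GCSAML, DNASE2, from 0.219 ± 0.048 to 17 ± 0.57 CPM, and RASGRP3. FPR1, HDC and SLC6A13 had at most 3 reads over both controls, so the size of their rises depends on the prior count. FPR1 and HDC are given as levels, FPR1 at 0.0291 and 8.52 CPM. Lists without a call after PU.1 knockdown were NF-kB (adjusted p = 0.091), cytosolic ribosomal proteins (0.14), epithelial and stromal genes (0.14), STAT5 targets (0.19), mitochondrially encoded genes (0.27), immediate early genes (0.32), glycolysis and hypoxia (0.37), T and NK lymphocyte genes (0.56), HOXA and MEIS1 (0.71), apoptosis regulators (0.71), B lymphocyte genes (0.71), megakaryocyte genes (0.79), chaperones of the endoplasmic reticulum (0.97) and leukemic stem cell score genes (1). The erythroid list, with 2 measured genes, was not tested.

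**Figure D2:**
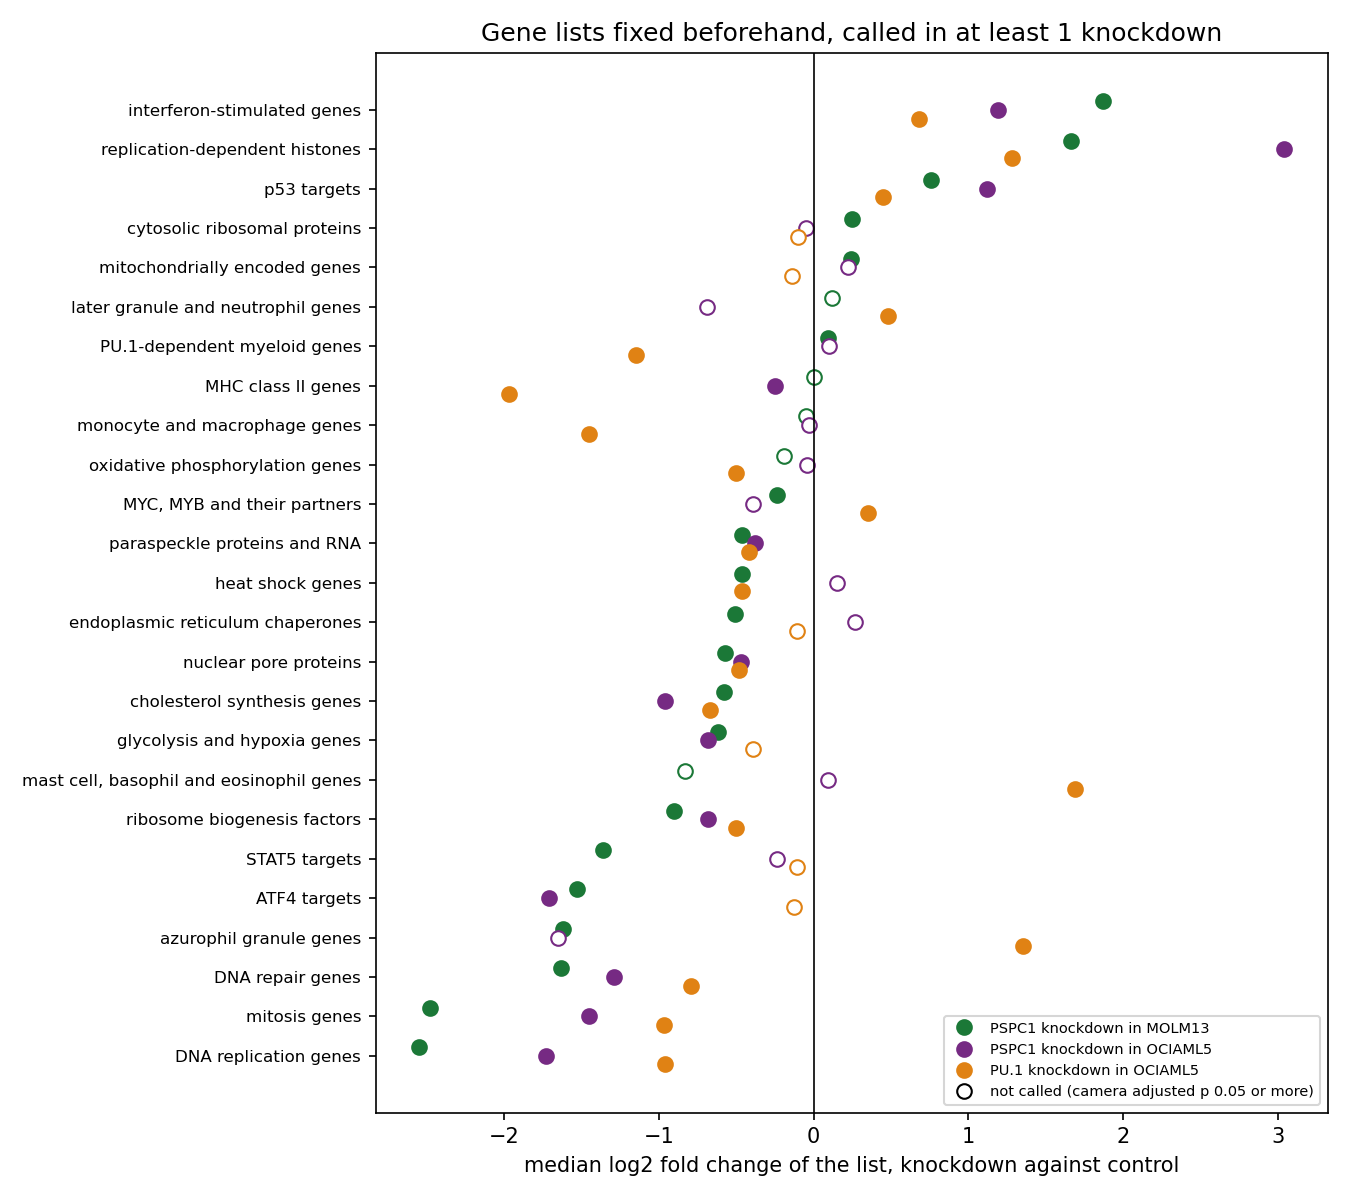
Median log2 fold change (horizontal axis) of each gene list called in at least 1 knockdown, with 1 point per knockdown comparison, coloured by comparison, filled where called at an adjusted p of 0.05 with the preset correlation and open where not (with an estimated correlation 11 of the 20 filled in MOLM13 and 0 of the 19 after PU.1 knockdown stay called). DNA replication genes lie at -2.55, -1.73 and -0.96 and ATF4 targets at -1.53, -1.71 and -0.13, the last being 0.02 with scaling by library size.

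The difference between the lines in the effect of PSPC1 knockdown was tested directly. Proliferation genes fell less in OCIAML5 than in MOLM13, and p53 targets rose more. MKI67 and CDKN1A, chosen for this comparison after their values were seen, had differences of effect of 1.40 and 1.16 on the log2 scale: MKI67 had log2 fold changes of -3.34 in MOLM13 and -1.94 in OCIAML5, and CDKN1A of 1.62 and 2.78. The difference of effects was positive for 26 of 27 mitosis genes (median 1.13, adjusted p = 1.7e-25), 25 of 28 DNA replication genes (0.85, adjusted p = 3.7e-20), 14 of 18 chaperones of the endoplasmic reticulum (0.63, adjusted p = 5.8e-13), 19 of 24 p53 targets (0.57, adjusted p = 3e-11) and 11 of 14 heat shock genes with 1 negative (0.72, adjusted p = 1.2e-09). In OCIAML5 itself camera called neither chaperone nor heat shock genes, so a rise beyond that of other genes is not shown for these lists. With fry, which does not compare them with other genes, both moved up on balance (adjusted p = 0.0047 and 0.0012). Of 18 chaperone genes 11 rose and 5 fell there, and of 14 heat shock genes 6 rose and 4 fell. The OCIAML5 controls used here stood below those of the PU.1 experiment for heat shock genes, p53 targets, chaperones and mitosis genes. The medians were -0.82, -0.44, -0.31 and -0.22 on the log2 scale, and only heat shock genes kept that call with an estimated correlation. The differences between the lines for these lists may therefore depend partly on the state of these controls. HSPA8 and HSPA5, 2 single genes chosen after their values were seen, had log2 fold changes of -0.99 and -0.35 in MOLM13 and of 0.53 and 0.72 in OCIAML5. FLT3, IRF8 and PIM1 were chosen in the same way: the difference of effects was -2.27 for FLT3 and -1.94 for IRF8, and PIM1, a STAT5 target, had log2 fold changes of -2.66 in MOLM13 and -0.40 in OCIAML5. The fall of PSPC1 itself did not differ detectably (-0.10, adjusted p = 0.52), while the difference was -0.31 for SPI1 and 0.28 for NDC1. Without knockdown replicate 2 of MOLM13 that of NDC1 was 0.25 (adjusted p = 0.087). In all, 5021 of 16457 genes (30.5%) differed, 2966 with a higher effect in OCIAML5 and 2055 with a lower one. A further 11 lists were called with the preset correlation and lost with an estimated one.

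Most genes that passed in both lines moved the same way. Of 6708 genes called after PSPC1 knockdown in both, 6106 (91%) had the same direction, 2804 higher and 3302 lower, where independent calls would give 1250 and 1380. At 2-fold the share was 97.1% (1552 of 1599). Across the 16457 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.52 and a Spearman correlation of 0.58. The genes called higher in MOLM13 had a median log2 fold change of 0.51 in OCIAML5 (p = 2.3e-32, and p = 5.4e-06 with an estimated correlation), and those called lower had a median of -0.50 (p = 1.4e-50, and p = 2e-05 with an estimated correlation).

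The effects of PU.1 and PSPC1 knockdown in OCIAML5 were compared in the 8 joined libraries, each knockdown against its own controls. ATF4 targets fell after PSPC1 knockdown and not, as a group, after PU.1 knockdown: the difference was positive for all 24 (median 1.54, adjusted p = 1.2e-27). MYC, MYB and BCL2, chosen after their values were seen, had differences of 1.57, 2.02 and 1.70 on the log2 scale, and SLC7A5, chosen likewise, of 1.96. MYC stood at 651 and 632 CPM in the control and PU.1-knockdown libraries, against 582 and 192 CPM in the PSPC1 experiment. Its log2 fold change after PU.1 knockdown was -0.04 (adjusted p = 0.36), or 0.11 with scaling by library size. PU.1-dependent myeloid genes had a lower effect after PU.1 knockdown in 21 of 29 cases and a higher one in 4 (median -0.90, adjusted p = 3.4e-12), with -5.42 for CSF1R, chosen likewise. MHC class II genes had a lower effect in 10 of 11 cases, 11 adjusted over the list alone (median -1.90, adjusted p = 1.7e-11). DNA replication genes fell less after PU.1 knockdown in 24 of 28 cases, 25 adjusted over the list alone, and more in 2 (median 0.75, adjusted p = 7.3e-11), and p53 targets rose less in 19 of 25 cases and more in 1 (median -0.63, adjusted p = 4.8e-10). These 5 lists kept their call with an estimated correlation, with adjusted p from 0.024 to 0.041, and 13 further called lists did not. Among those, 3 lists had an adjusted p of 0.055 with an estimated correlation: azurophil granule genes with a higher effect after PU.1 knockdown in 11 of 13 cases (median 2.38), MYC, MYB and partners in 6 of 9 with 1 lower (0.85), and heat shock genes with a lower effect in 12 of 14 with 1 higher (-0.76). In the PSPC1 experiment 3 of the 13 azurophil genes had at most 3 counts in a group. A floor of 3 counts moved their median after PSPC1 knockdown from -1.65 to -0.45, so the value of 2.38 depends on such genes. The largest differences by the naming rule were those of TRDV2, HDC, IGLL1, ADGRG3 and FGFBP2 upward and of GAPT, PTPRO, FCER1A, FGD2 and CLECL1 downward. Apart from GAPT and FCER1A, with 11 and 6 reads after PU.1 knockdown, each has a group of at most 3 reads. The size of those differences therefore depends on the prior count. HDC (adjusted p = 1) and ADGRG3 (adjusted p = 0.058) lost their call without control replicate 2 of the PSPC1 experiment. GAPT rose from 6.9 ± 1.6 to 32.5 ± 3.8 CPM after PSPC1 knockdown and fell from 12.4 ± 0.52 to 0.174 ± 0.0098 CPM after PU.1 knockdown. In all, 7832 of 17159 genes (45.6%) differed, 3905 upward and 3927 downward. The controls of the 2 experiments were not alike: ATF4 targets were higher in the controls of the PSPC1 experiment for 23 of 24 genes (median 1.29 on the log2 scale), and p53 targets were lower there for 15 of 25 (median -0.44, adjusted p = 1.6e-05, and adjusted p = 0.086 with an estimated correlation), and heat shock genes were lower for 14 of 14 (median -0.82, adjusted p = 7.9e-36, and adjusted p = 0.0089 with an estimated correlation). For these 3 lists the difference of effects runs the same way as the difference of the controls. In all, 14 of 35 lists differed between the controls, of which only ATF4 targets, MHC class II, heat shock and PU.1-dependent genes kept their call with an estimated correlation.

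**Figure D3:**
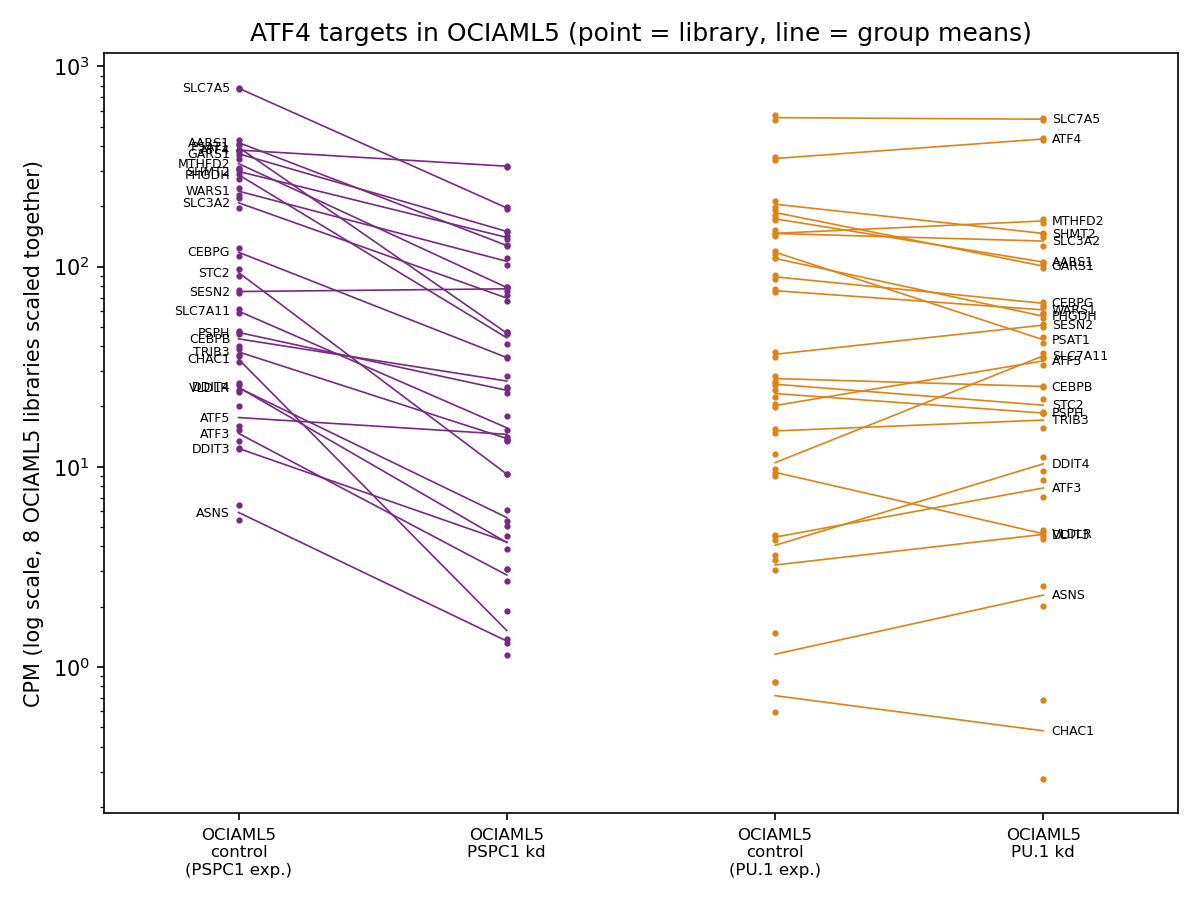
Level in CPM (log axis, the 8 OCIAML5 libraries scaled together) of the 24 ATF4 targets in the control and knockdown groups of both experiments, with points for libraries and lines joining the group means of each gene. The targets start higher in the controls of the PSPC1 experiment, by a median of 1.29 on the log2 scale, and drop after PSPC1 knockdown, with a median log2 fold change of -1.71.

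The changes after both knockdowns in OCIAML5 overlapped in part. Of 6527 genes called after both, 4999 (76.6%) had the same direction, 2145 higher and 2854 lower, where independent calls would give 1279 and 1539, and at 2-fold 872 of 974 (89.5%) did. The correlations across 15396 genes were 0.40 (Pearson) and 0.43 (Spearman). No control library was shared. Genes called higher after PSPC1 knockdown had a median of 0.25 after PU.1 knockdown (p = 1.3e-07, and p = 0.0011 with an estimated correlation), and those called lower a median of -0.35 (p = 2.9e-17, and p = 0.0058 with an estimated correlation). Between PSPC1 knockdown in MOLM13 and PU.1 knockdown, 4787 of 6510 genes (73.5%) had the same direction. In all 3 knockdowns 1479 genes were higher and 2211 lower, where independent calls would give 355 and 470, and a further 1360 were called in all 3 with mixed directions. CCR2, the receptor of the chemokine CCL2 (chromosome 3, 46353734 to 46360928), fell from 119 ± 5.5 to 14.2 ± 1.9 CPM, from 52.2 ± 2.1 to 5.73 ± 1.1 CPM and from 42.4 ± 1.4 to 6.69 ± 0.23 CPM in turn. TERT, the catalytic subunit of telomerase (chromosome 5, 1253147 to 1295069), fell from 14.8 ± 1.1 to 1.48 ± 0.14 CPM, from 9.18 ± 0.47 to 0.737 ± 0.021 CPM and from 8.45 ± 0.1 to 1.57 ± 0.043 CPM. INHBA, COL15A1 and TMEM45A completed the downward set of the naming rule, and LINC00672, SLC6A13, IFI44L, FLG-AS1 and HFE formed the upward one. LINC00672, SLC6A13 and HFE had at most 8 reads over the controls of any comparison. In OCIAML5, FLG-AS1 had 2 reads over the controls of the PSPC1 experiment, and INHBA and COL15A1 had 3 each after PSPC1 knockdown. The size of these changes therefore depends on the prior count. FLG-AS1 lies opposite to FLG, FLG2 and HRNR. LINC00672 in MOLM13 lost its call without knockdown replicate 1 (adjusted p = 0.061), and TMEM45A after PU.1 knockdown lost it without control replicate 1 (adjusted p = 0.059), control replicate 2 (0.081) or knockdown replicate 2 (0.2).

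**Figure D4:**
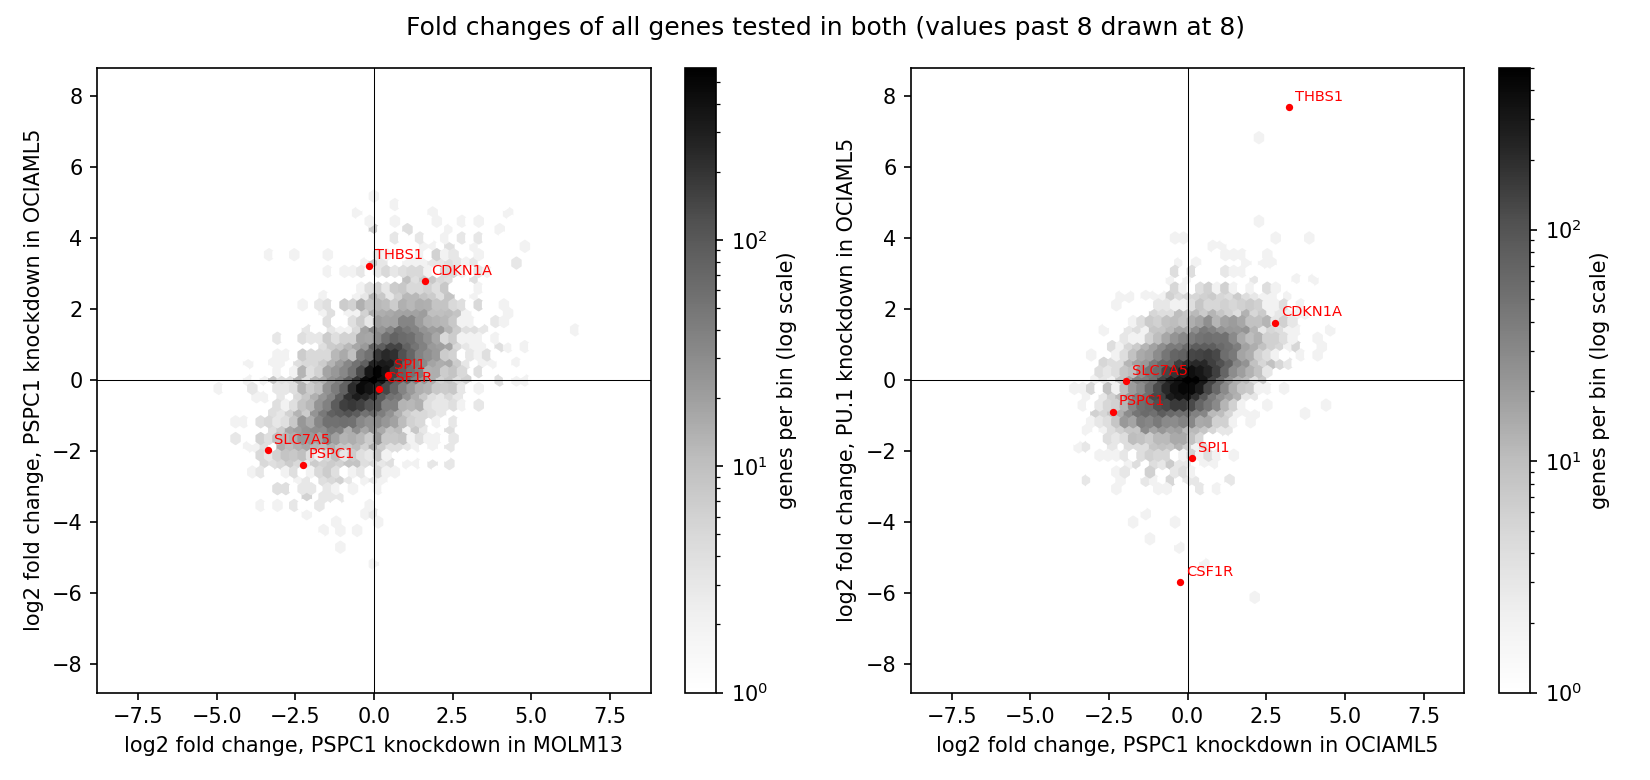
Log2 fold changes of all genes tested in both comparisons, with shading for the number of genes per bin (log scale) and red points for named genes: PSPC1 knockdown in MOLM13 (horizontal) against OCIAML5 (vertical) on the left, and PSPC1 (horizontal) against PU.1 knockdown (vertical) in OCIAML5 on the right. The Pearson correlation across genes is 0.52 on the left and 0.40 on the right.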

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

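The test of short genes and both tests of the direction shared by the knockdowns were set down before their results were seen; the tests on RNAs without a poly(A) tail, S phase, the ATF4 control level, the ATF4 proportion and the proportion over all lists were chosen after.

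The effect of PSPC1 knockdown differed between OCIAML5 and MOLM13 for 5021 genes, by a test of the difference between the lines. The same test singled out 16 gene lists, whose median differences of the log2 fold change (OCIAML5 minus MOLM13) were 1.13 for mitosis, 0.85 for DNA replication, 0.63 for endoplasmic reticulum chaperones, 0.57 for p53 targets, 0.72 for heat shock genes, 0.84 for STAT5 targets, 0.30 for DNA repair, 0.19 for ribosome biogenesis factors, 1.31 for histones and 0.19 for paraspeckle genes. They were -0.26 for cytosolic ribosomal proteins, -0.38 for interferon-stimulated genes, -0.30 for cholesterol synthesis, -0.12 for the HOXA and MEIS1 program, -0.56 for MHC class II and -0.02 for PU.1-dependent genes, the last having a mean of 0.03 and a median of 0.02 with scaling by library size. Mitosis, DNA replication, chaperones, p53 targets and heat shock genes kept their call with an estimated correlation. All of these but DNA replication were called lower in these OCIAML5 controls than in those of the PU.1 experiment with the preset correlation. Their differences between the lines may therefore depend partly on the state of the controls.

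Single genes that differed by the same test were SPI1 (-0.31), NDC1 (0.28), TRPA1 (6.96), RALGPS2 (6.32), CXCL10 (6.08), EVPL (5.85), HEG1 (5.66), GPNMB (-8.10), KCNN2 (-6.21), HIPK2 (-5.74), ERG (-5.62) and FIRRE (-5.61). From TRPA1 on, each has a group near 0 reads, so these fitted values depend on the prior count and bound nothing. Without 1 library CXCL10, EVPL, HIPK2, ERG and FIRRE lost their call. The differences were 2.57 for CXCL10 and 1.41 for EVPL without OCIAML5 knockdown replicate 1, and -4.61 for HIPK2 without OCIAML5 control replicate 1. They were -5.59, -5.65 and -5.19 for ERG without MOLM13 control replicate 1, control replicate 2 or knockdown replicate 2, and -0.58 for FIRRE without MOLM13 knockdown replicate 2. Genes chosen after their values were seen were FLT3 (-2.27), IRF8 (-1.94), PIM1 (2.26), CDKN1A (1.16), MKI67 (1.40), HSPA8 (1.52), HSPA5 (1.06) and NEAT1 (-0.58).

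Histone mRNAs were higher after PSPC1 knockdown in both lines, with list medians of 1.66 and 3.04, and 9 of 15 were higher after PU.1 knockdown (median 1.28), where the list lost its call with an estimated correlation (adjusted p = 0.33). If poly(A) selection had been weaker in the knockdown libraries, other RNAs without a poly(A) tail would have risen too. Their median after PSPC1 knockdown was 0.05 (SE 0.42) in MOLM13 and 0.24 (SE 0.94) in OCIAML5, from 6 genes whose spread by itself leaves this cause open. In OCIAML5 their summed level was 9.25 ± 1.2 CPM in the controls and 9.37 ± 1.17 CPM after knockdown, while the histone sum went from 24.5 to 242 CPM. The sum of the other RNAs did not rise with the histones, but a sum of few RNAs can rest on 1 of them, so the cause stays open in OCIAML5. In MOLM13 both sums rose and it stays open too. After PU.1 knockdown the median was -0.60 (SE 0.42), which argues against it there. In OCIAML5 after PSPC1 knockdown, 1623 other short protein-coding genes had a median of -0.02 (SE 0.034). These were no longer than the longest histone gene of the list, 2411 exonic bases. This argues against a bias over that whole range of lengths, but a bias confined to the shortest genes was not tested. More cells in S phase predicted a rise of DNA replication genes, and these fell (-1.73). The mRNA levels of these genes do not measure the share of cells in S phase, so the test does not decide this. Polyadenylated histone transcripts, known from cells outside S phase, may contribute, and this was not tested.

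ATF4 targets fell after PSPC1 and not, as a group, after PU.1 knockdown in OCIAML5. They were already higher in the controls of the PSPC1 experiment, by a median of 1.29 (SE 0.29), against a difference of effects of 1.54, so a different state of the control cultures may account for much of it. A change in proportion to the loss of PSPC1 mRNA predicts -0.64 after PU.1 knockdown if the fall is taken from the PSPC1 controls, and -0.14 if the PSPC1 knockdown is set against the PU.1 controls. The median found was -0.13 (SE 0.2), or 0.02 with scaling by library size, so the test turns on which controls are used and decides nothing. The size of the fall after PSPC1 knockdown in OCIAML5 depends on the controls too. Its median was -1.71 against its own controls and -0.38 (SE 0.2) against those of the PU.1 experiment. An effect particular to PSPC1 stays open as well.

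Changes after PU.1 knockdown went the same way as after PSPC1 knockdown in OCIAML5 for 76.6% of the genes called in both. Trends with gene length, GC content and expression level do not account for this, since the correlation was 0.38 after their removal and 0.41 before. The fall of PSPC1 mRNA after PU.1 knockdown may contribute: over genes called at 2-fold in MOLM13 the slope of the PU.1 on the PSPC1 effect was 0.41 (SE 0.013), near the ratio of the PSPC1 falls, 0.38. This SE and those of the list medians below treat genes as independent replicates, which they are not, so they understate the error. A slowed cell cycle common to both knockdowns would also give such a slope and was not tested. Of 33 lists, 18 had a median after PU.1 knockdown within 2 SE of their PSPC1 median times that ratio, some with wide errors, and 15 did not, so the fall of PSPC1 by itself leaves many lists unaccounted for, as far as the PSPC1 controls can serve as a baseline.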

How the results depend on the processing

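Scaling by library size alone, and RLE size factors for lists, were chosen after the data were seen, and the other alternatives before. Where a library was left out, the lone library of its group was assumed to vary like the other groups.

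The 2-fold minimum lowered the genes called to 3425 and 3136 after PSPC1 knockdown in MOLM13 and OCIAML5, 2954 after PU.1 knockdown, 1381 for the difference between the lines and 2598 for that between the knockdowns, as its construction requires. With an estimated correlation 11 of 20 lists were called in MOLM13, 0 of 19 after PU.1 knockdown, where fry called 28, and 5 in each difference test. With fry 26 lists were called after PSPC1 knockdown in OCIAML5, 27 for the difference between the lines and 28 for that between the knockdowns, as it does not compare a list with other genes.

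The log2 fold change of SPI1 after PSPC1 knockdown in OCIAML5 lost its call with DESeq2 (0.13, adjusted p = 0.053) and with the 4 libraries of the line alone (0.13, adjusted p = 0.059), and ran from 0.05 to 0.21 without 1 library; the cause was not tested. That of MYC after PU.1 knockdown, not called as reported, turned to 0.11 (adjusted p = 0.0079) with scaling by library size, which shifts the median of all genes there by 0.152. Of 2998 checks on 269 results of named genes, 2967 kept their side of the threshold, 22 lost their call and 8 gained one. The remaining 1 was the reversal of MYC. Results not called in either setting were counted among the 2967 even if their direction changed. Most of the named genes were chosen for large changes or a small adjusted p, or after their values were seen, so these counts do not describe other genes.

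Without 1 library the genes called ran from 8192 to 8387, 8055 to 8418, 8765 to 9443, 4354 to 4832 and 6919 to 7636 in the 5 comparisons in turn. With a replicate block they were 9289, 9125, 9941, 4971 and 7688, and with DESeq2 8819, 8585, 8282, 4600 and 6634. In data simulated at these depths with 2 libraries per group, a log2 change of 0.3 was recovered for 4% of genes in the difference between the lines. Far fewer genes changed in that simulation than were called in the data, so the share need not carry over.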

Other observations

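The comparison of both control groups of OCIAML5 was chosen after the results were seen. Between the controls of the PSPC1 and PU.1 experiments 6681 of 17159 genes passed, 3250 higher and 3431 lower in the PSPC1 experiment. All 11 MHC class II genes were higher there (median 1.20, adjusted p = 1.3e-28), as were 23 of 24 ATF4 targets (1.29, adjusted p = 4.3e-56), and all 14 heat shock genes were lower (-0.82, adjusted p = 7.9e-36); each had an adjusted p of 0.0089 with an estimated correlation. PU.1-dependent myeloid genes were higher for 16 of 29 and lower for 4 (median 0.37, adjusted p = 3.2e-06, and 0.042 with an estimated correlation). CHAC1 stood at 34.5 and 0.718 CPM, PSAT1 at 395 and 118 CPM and SLC7A11 at 59.9 and 10.5 CPM in the controls of the PSPC1 and PU.1 experiments. The PSPC1-knockdown libraries set against the controls of the PU.1 experiment gave a median of -0.38 (SE 0.2) for ATF4 targets.

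The 10 genes with the most counts took 10.8 to 11.9% of each control library in the PSPC1 experiment and 14.1 to 14.8% after PSPC1 knockdown.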
